A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

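Chromatin immunoprecipitation on tiling arrays was measured in fission yeast, Schizosaccharomyces pombe, for FLAG-tagged Abp1 on 2 arrays and for FLAG-tagged Cbh1 on 2 arrays. Per the labels' protocols, asynchronous cultures at 30 °C were fixed with paraformaldehyde for 30 min at 18 °C and then with dimethyl adipimidate for 45 min. Chromatin was sheared by bead beating and sonication, and the recovered DNA was amplified by random priming. Immunoprecipitated DNA carried Cy5 and whole cell extract DNA carried Cy3 on every array, so no dye swap separates a dye effect from enrichment. Groups and replicate numbers came from the sample titles. No untagged or mock immunoprecipitation was used here, so each ratio sets a tagged protein's DNA against whole cell extract only.

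The scanner files hold spot intensity values made with Feature Extraction 8.1.1.1 on 3 arrays and 8.5.1.1 on Cbh1 replicate 2, per the file headers. Per the file headers, the processed intensity values had no background subtraction and were dye-normalized within each array by linear scaling and LOWESS. Before deposit, the authors' software also wrote a log10 ratio of the processed Cy5 over Cy3 intensity for each spot, per the file headers, and this column was only checked against the intensities. The authors' deposited value table is on a log2 scale. Against the log2 ratio of the median Cy5 over Cy3 spot intensity of the same array, its columns had slopes of 1, correlations across probes of 0.99998 to 0.99999 and SDs of the difference of 0.0029. Its column medians were -0.06 for Abp1 replicate 1 and -0.04 for each of the other 3 arrays. Scale and direction were thereby settled, and the constant that sets each column's centring stays unknown. The tool that made the value table and the genome build of the array design are not given in the sources used here.

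All 41551 probes other than controls are 60 bases long, and each sequence was matched exactly, on both strands, to assembly ASM294v3. Of these, 40396 had 1 match, 1053 had several and 102 had none. All 40238 probes with 1 match that were named for a chromosome matched that chromosome. Probes with several matches were placed on the chromosome in their name, at the match nearest to their named position after the local offset between design and assembly was removed. In all, 41350 probes were placed on chromosomes I to III, with a median spacing of 300 bp. Coordinates are 1-based positions in ASM294v3 from this match. The array's own coordinates were not printed.

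The log2 ratio of processed Cy5 over Cy3 intensity was centred on each array's median over the probes other than controls, without loess or quantile normalization. Spots that the scanner software marked as outliers were left out, and saturated spots were kept. Outlier spots numbered 6291 on Abp1 replicate 1 (15.1%), 7952 on Abp1 replicate 2 (19.1%), 1232 on Cbh1 replicate 1 (2.97%) and 313 on Cbh1 replicate 2 (0.75%). As a result, 10911 of the 39885 probes measured for Abp1 and 1521 of the 41539 measured for Cbh1 had a value on 1 array only. Outlier marks were more frequent among probes with a mean log2 ratio of at least 1, at 36.4% of these against 18.3% of other probes on Abp1 replicate 2. A fit that kept these spots was therefore added after the data were examined.

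Enrichment was tested in limma 3.58.1 under R 4.3.3 with lmFit and eBayes on a model with 1 mean per group over all 4 arrays, so that both groups shared 1 estimate of the spread. Benjamini-Hochberg (BH) adjustment ran over all probes. A probe was called enriched at an adjusted p under 0.05 and a mean log2 ratio of at least 1, and the difference Abp1 minus Cbh1 was called at an adjusted p under 0.05. The prior had 14.12 degrees of freedom and an SD of 0.145, so a probe measured on 1 array of a group took its spread from the other group and from this prior, and with 1 array in both groups from the prior alone. Enriched regions were runs of at least 2 neighbouring enriched probes with centres at most 1000 bp apart. Overlaps of at least 1 bp were set against 1000 circular shifts of the regions along each chromosome.

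The 13 feature classes came from the assembly's annotation: Tf2 elements, long terminal repeats (LTRs) outside Tf2, centromeres, the terminal 50 kb of chromosomes I and II, the terminal 20 kb of chromosome III, tRNA and 5S rRNA genes with 250 bp on each side, gene bodies, intergenic sequence by the orientation of its neighbours, the mitochondrial genome and mating-type probes. Centromeres were taken from the first to the last annotated centromeric transcript, because their inner parts are not annotated in the reference. The reference does not annotate the mat2-mat3 interval, so the 110 probes named for the mating-type region on the array were used in its place, and 36 of them had no match in ASM294v3. Replication origins are not annotated in the reference and were not analysed here. Each class was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, on the probes measured on all 4 arrays. With 4 arrays, the estimated form has few residual degrees of freedom and so little power. Class means were also set against 10000 circular shifts of the class labels, except for mitochondrial and mating-type probes. BH adjustment ran over the classes.

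A gene's upstream value was the mean over probes centred within 500 bp upstream of the annotated start, fitted in the same model. The 12 gene lists covered the CENP-B family, the G1-S transition, chaperones, core stress, glycolysis and fermentation, histones, iron and copper, mating and meiosis, nitrogen and nutrient transport, phosphate, ribosomal proteins and silencing. Genes were named by rule: the CENP-B family, every Tf2 element with probes, the genes of the 15 highest regions per protein with both arrays above 1, the 10 highest and 10 lowest regions of the difference, up to 3 highest and 2 lowest members of each list, and the highest probe of each class. Regions that held probes of the Tf2, LTR, centromere, mating-type, subtelomere or mitochondrial class were left out of the ranking. This rule, the lists, the classes, the tests and all alternatives but the added one were fixed before the data were examined. Bins within Tf2 elements, bins of LTR length, subsets of classes and the profiles around LTRs were chosen after values had been seen.

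The scripts, under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, were tested on simulated data whose noise was drawn from the fitted prior for 41549 probes. Recovery was counted at an adjusted p under 0.05 alone. It is therefore not the sensitivity of the enriched calls, which also need a log2 ratio of at least 1. For Abp1, 49 of 65 probes changed by 0.585 (75.4%), 62 of 63 changed by 1 (98.4%) and 64 of 64 changed by 2 were recovered, with 14 of 39693 unchanged probes called. For Abp1 minus Cbh1, 13 of 65 probes changed by 0.585 (20%) and 58 of 63 changed by 1 (92.1%) were recovered, with 10 of 39683 unchanged probes called. On simulated Abp1 arrays, camera gave an unadjusted p under 0.05 for 3 of 100 random sets over 28363 probes. In these simulations the noise was independent between probes and no shift was shared across an array. The recovery and camera rates are thus best cases and do not cover classes of neighbouring, correlated probes.

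The alternatives were normexp background correction (offset 50), within-array loess (span 0.3), the value table, a filter on dim probes, removal of saturated spots, centring on gene bodies, trended and robust eBayes, removal of a GC trend, other thresholds of 0.585 and 1.5, a rule of log2 1 on both arrays, other run lengths, gaps, overlap rules and upstream windows, gene bodies in place of upstream windows, only probes with 1 match, class medians, the replicate number as a block, and leaving out each array. Without 1 array, the remaining array of that group was assumed to vary like the other group. Each array was on its own slide with its own scan, so no batch held over 1 array, slide was not run as a block, and slide and array cannot be told apart. Nothing in the sources says that the replicates came from separate cultures, so each p measures only the spread between these samples, which may be technical. The number of arrays, 2 per group, limits the precision.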

Results

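The genome-wide binding of Abp1 and Cbh1 was profiled in fission yeast. Both are proteins of the CENP-B family, which is related to the transposases of DNA transposons, and the series title places them in the surveillance of retrotransposons. FLAG-tagged Abp1 was measured on 2 arrays and FLAG-tagged Cbh1 on 2 arrays. Each array compared immunoprecipitated DNA (Cy5) with whole cell extract (Cy3) over 41551 probes, and 0 on the log2 scale is the array median. Median signal over background in the Cy3 channel was 4.81 and 5.06 on the Abp1 arrays and 4.30 and 4.70 on the Cbh1 arrays. In the Cy5 channel it was 5.14 and 5.58 for Abp1 and 4.62 and 5.83 for Cbh1. Across probes, which are not independent replicates, Pearson's r was 0.872 between the Abp1 arrays (28974 probes) and 0.916 between the Cbh1 arrays (40018 probes), and 0.599 to 0.698 between arrays of different proteins. The number of arrays limits the precision, and nothing says that replicates came from separate cultures, so each p measures only the spread between these samples. Levels are means ± SD over the 2 arrays of a protein, and differences are means of limma contrasts over the probes measured for both proteins. Coordinates are in ASM294v3.

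The first comparison asked where each protein was enriched over whole cell extract. The 13 full-length Tf2 elements, LTR retrotransposons of fission yeast, were enriched for both proteins. Tf2 probes had a mean log2 ratio of 1.48 ± 0.07 for Abp1 and 1.95 ± 0.07 for Cbh1 (SD, n = 2 arrays each), with 65 of 91 measured probes called enriched for Abp1 and 94 of 94 for Cbh1. Solitary and other long terminal repeats outside Tf2 had 1.82 ± 0.43 for Abp1 and 1.37 ± 0.03 for Cbh1, with 97 of 116 and 88 of 133 probes enriched. Of the 211 annotated LTRs outside Tf2, 154 (73.0%) overlapped an Abp1 region, 110 (52.1%) a Cbh1 region and 102 both. Tf2 probes stood above the other probes in camera (limma) with a preset correlation for Abp1 (adjusted p = 3.86e-45) and Cbh1 (adjusted p = 4.60e-65), and also with an estimated correlation (adjusted p = 0.0386 and 0.0266). That correlation was estimated at -0.015 for Tf2 probes, although 85 of the 94 match the genome several times, so this pass may be too easy. LTR probes did so with the preset correlation (adjusted p = 4.53e-37 for Abp1 and 2.58e-30 for Cbh1), a call that was lost with the estimated one (adjusted p = 0.223 and 0.400 with an estimated correlation). In circular shifts of the class labels, both classes reached the smallest p that 10000 shifts allow, which was 0.000275 for Abp1 and 0.000440 for Cbh1 after adjustment.

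**Figure D1:**
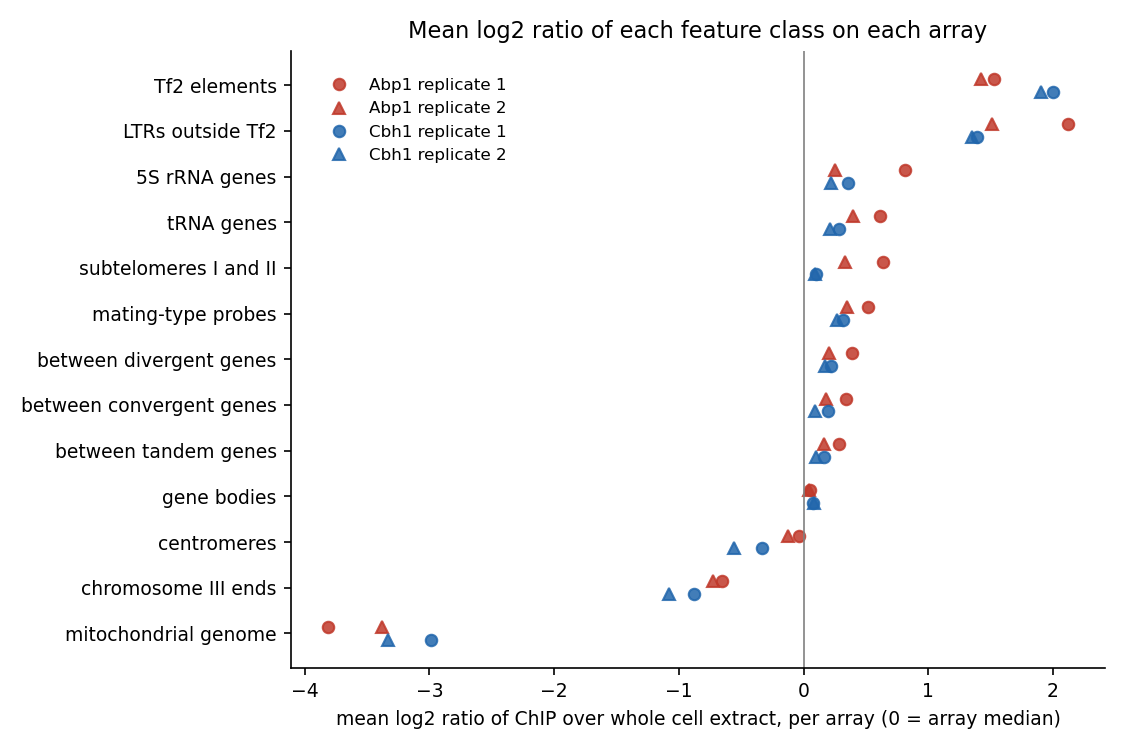
Mean log2 ratio of immunoprecipitated DNA over whole cell extract for each of the 13 feature classes, with 1 point per array and 0 at the array median. Tf2 elements and LTRs lay highest for both proteins, centromere probes at or below 0, and mitochondrial probes lowest.

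Every Tf2 element with probes had a mean log2 ratio above 1, at 1.1 to 1.94 for Abp1 and 1.67 to 2.13 for Cbh1. These element values are means of the fitted probe values, not of the 2 array means. The highest Abp1 value, at Tf2-10, came with array means of 1.845 and 0.965. For Abp1, only 1 of the 2 probes of Tf2-10 and 1 of the 3 of Tf2-7 were called enriched. Tf2-4 (chromosome I, 3361148-3366062), the element with the most probes, had 1.58 for Abp1 and 1.99 for Cbh1 over 16 probes. Tf2-1 (I, 1465332-1470247) had 1.89 and 2.12 over 6 probes, and Tf2-8 (I, 5195312-5200657) had 1.60 and 2.13 over 14. Tf2-12 (III, 777734-782649) had 1.35 and 1.88 over 10 probes, and Tf2-11 (II, 4414197-4419057) had 1.1 and 1.67 on its 1 probe. Of the 94 Tf2 probes, 85 match the genome several times, so the elements share most of their signal. Within 400 bp of an element end, Abp1 had 2.38 ± 0.35 and Cbh1 2.16 ± 0.21 over 15 probes (n = 2 arrays each). Between 2000 and 2800 bp from the nearer end, Abp1 had 0.84 ± 0.25, with 1 of 20 probes enriched, and Cbh1 had 1.54 ± 0.02, with 20 of 20 enriched. At the centres of LTRs at least 5 kb from a Tf2 element, the mean log2 ratio was 1.60 for Abp1 and 1.23 for Cbh1. Abp1 replicate 1 stood at 1.95 there, Abp1 replicate 2 at 1.25 and the Cbh1 arrays at 1.22 and 1.25. Of the LTRs of at least 300 bp, 138 of 168 (82.1%) overlapped an Abp1 region and 100 (59.5%) a Cbh1 region, against 4 and 3 of the 16 LTRs shorter than 200 bp. The bins of position and of length were chosen after the values had been seen.

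**Figure D2:**
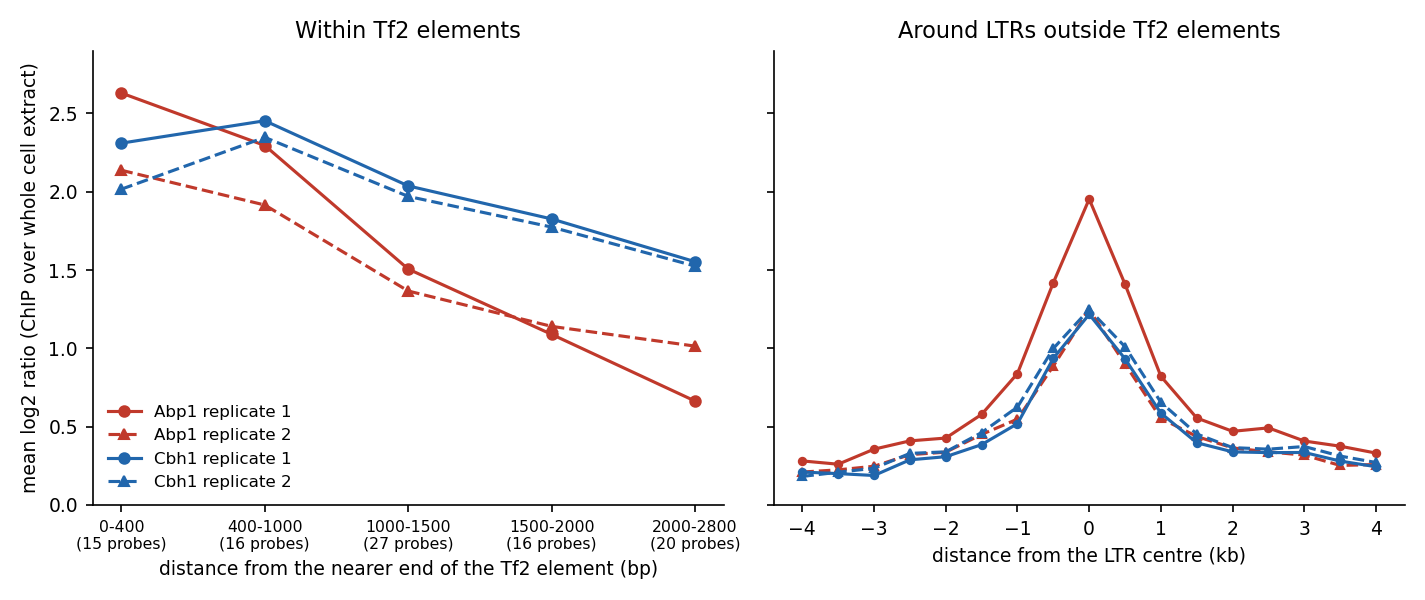
Mean log2 ratio per array by distance from the nearer end of a Tf2 element (left, bp) and by distance from the centre of LTRs at least 5 kb from a Tf2 element (right, kb). Abp1 fell from 2.38 near the element ends to 0.84 in the middle and Cbh1 from 2.16 to 1.54, and around LTRs Abp1 replicate 2 overlay both Cbh1 arrays.

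In all, 2280 of 39885 probes (5.72%) were enriched for Abp1 and 2062 of 41539 (4.96%) for Cbh1, and 1021 were enriched for both, while 115 and 141 probes were depleted, at a log2 ratio of -1 or lower. The enriched probes formed 453 Abp1 regions with a median width of 1014 bp and 244 Cbh1 regions with a median of 1468 bp. Cbh1 regions of at least 3000 bp numbered 65, against 21 for Abp1. Of the Abp1 regions, 215 (47.5%) overlapped a Cbh1 region, where circular shifts gave 31.7 on average, and 202 of the Cbh1 regions (82.8%) overlapped an Abp1 region, where shifts gave 30.3. Annotated LTRs outside Tf2 were overlapped by 132 Abp1 regions (29.1%, with 10.6 by chance) and 93 Cbh1 regions (38.1%, with 8.7 by chance). The permutation p from these shifts was 0.000999 for all of these overlaps, the smallest that 1000 shifts allow. Such shifts test against random placement only. Without a mock immunoprecipitation, probe effects shared by the arrays cannot be told from binding shared by the proteins. Most regions overlapped no annotated retrotransposon sequence, although some of these lay close to an LTR. Of the Abp1 regions, 301 overlapped no annotated LTR or Tf2 element, and 196 of these overlapped no Cbh1 region either, with mean log2 ratios of 1.42 for Abp1 and 0.25 for Cbh1. Of the Cbh1 regions, 135 overlapped no LTR or Tf2 element, with a median width of 1825 bp. The 92 that overlapped an LTR and no Tf2 element had a median of 1304 bp. Among the 135, the 98 that overlapped an Abp1 region had a median of 2722 bp, and the 37 that did not had 583 bp. Without Abp1 replicate 1, the Abp1 counts were 1210 probes and 289 regions, of which 148 overlapped a Cbh1 region. Normexp background correction gave 4031 and 3435 enriched probes. Which protein had more enriched probes depended on the rule. A log2 ratio of 1 on both arrays without a test gave 879 Abp1 and 1612 Cbh1 probes in 231 and 222 regions, with an overlap of 115, and a threshold of 1.5 gave 1051 and 1214 probes, with 260 Abp1 regions and an overlap of 131.

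**Figure D3:**
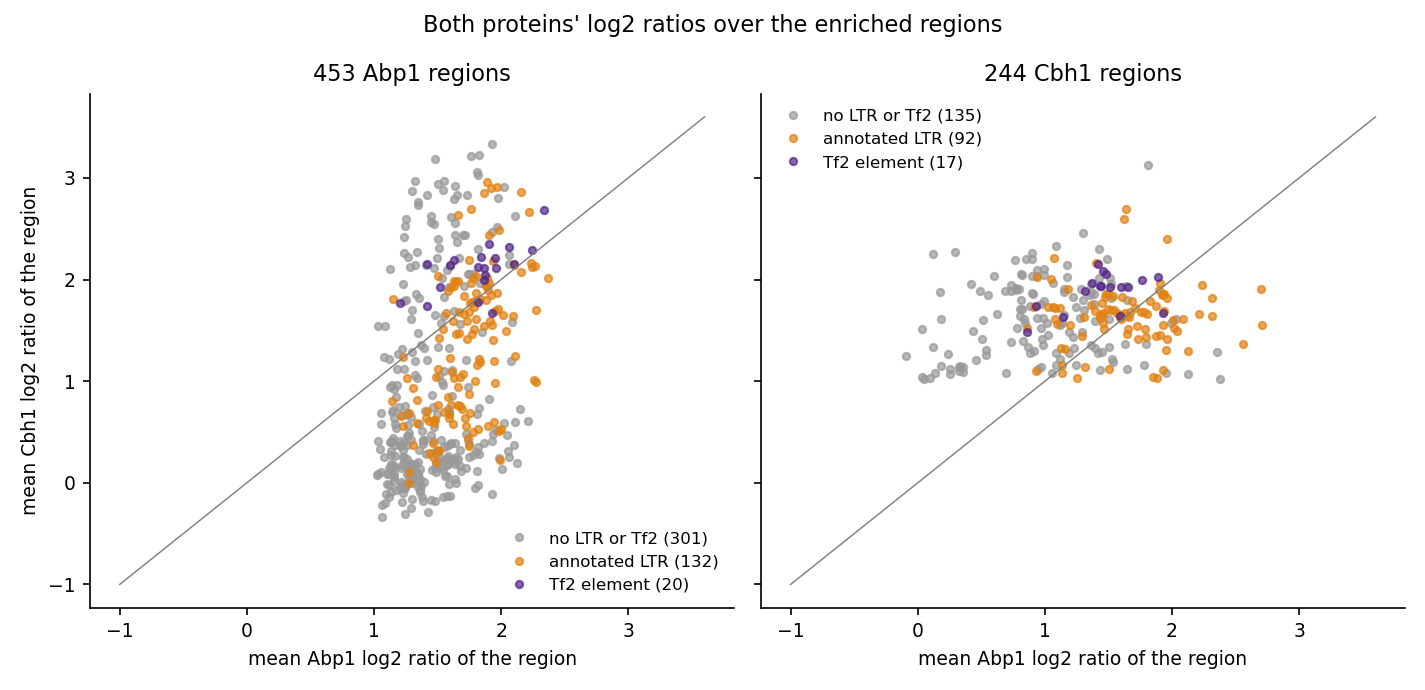
Mean log2 ratio of Abp1 (x axis) and Cbh1 (y axis) over each of the 453 Abp1 regions (left) and 244 Cbh1 regions (right), with 1 point per region coloured by overlap with an annotated LTR or a Tf2 element and a line of equal ratios. The 301 Abp1 regions without LTR or Tf2 include a dense group with Cbh1 ratios near 0.

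Outside retrotransposons, Abp1 was highest at a set of loci where Cbh1 was mostly lower. Upstream of spa1 and in sim3, a histone chaperone gene (II, 780195-781612), the ratio was 2.03 ± 0.43 for Abp1 and 0.61 ± 0.03 for Cbh1 (SD, n = 2 arrays each). Over the 3' part of cdc22, which encodes the large subunit of ribonucleotide reductase, and the neighbouring hsp3105 (I, 4229249-4231470), it was 2.11 ± 0.33 and 0.19 ± 0.01. At the spindle checkpoint gene mad1 (II, 1276042-1277237) it was 1.98 ± 0.35 and 0.37 ± 0.04, and at pdi3 (II, 1294813-1297067) 2.10 ± 0.19 and 0.59 ± 0.04. Between svf1 and mug42 (III, 1513721-1514760) it was 2.06 ± 0.46 and 0.73 ± 0.06, and at vht1, the biotin transporter gene (I, 4960587-4962296), 2.10 ± 0.21 and 1.20 ± 0.08. Other high Abp1 regions were high for Cbh1 too. Between fum1, encoding fumarase, and rpc34, encoding an RNA polymerase III subunit (III, 1990694-1993935), the ratio was 2.14 ± 0.03 for Abp1 and 2.67 ± 0.15 for Cbh1. At rnh1/sfc3 (II, 2749594-2750929) it was 1.79 ± 0.51 and 2.15 ± 0.16, and at toc1/rpl35A02/rad60 (II, 2405201-2407124) 2.12 ± 0.38 and 1.56 ± 0.02. The other 6 regions named by the rule overlapped an annotated LTR that holds no probe of the LTR class. They were nop52/clc1 (2.10 ± 0.40), mis4/atp25 (1.87 ± 0.69), gmh6/SPBC1289.14 (2.16 ± 0.51), SPCC794.16/SPCC794.06 (2.02 ± 0.56), pet3/SPAC22E12.02 (2.09 ± 0.26) and SPCC576.02/tpx1/bxi1 (1.93 ± 0.31). Without Abp1 replicate 1, mis4/atp25 (1.39), nop52/clc1 (1.82) and pet3/SPAC22E12.02 (1.91) no longer passed.

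The highest Cbh1 regions without an LTR probe were mostly wide. The highest mean lay at I, 4528282-4528734, where no protein-coding gene is annotated, with 3.13 ± 0.23 for Cbh1 and 1.81 ± 0.54 for Abp1 (SD, n = 2 arrays each). A region of 6688 bp at SPAPB1A11.02, mca1 and SPAPB1A11.03 (I, 2979708-2986395) had 2.52 ± 0.07 for Cbh1 and 1.33 ± 0.23 for Abp1. Over apc5, an anaphase-promoting complex gene (I, 3404112-3408417), the ratio was 2.33 ± 0.12 for Cbh1 and 1.09 ± 0.30 for Abp1. Upstream of kgd1, encoding a 2-oxoglutarate dehydrogenase subunit (II, 1874251-1878564), it was 2.27 ± 0.10 and 0.29 ± 0.05, and over the splicing helicase gene prp28, the proteasome gene pup3, SPCC63.13 and eis1 (III, 858751-862761) 2.20 ± 0.05 and 0.12 ± 0.07. At bio2, encoding biotin synthase (III, 173847-178366), it was 2.23 ± 0.07 and 0.87 ± 0.04, and at rad17 and the ATP synthase gene atp1 (I, 5253635-5258667) 2.12 ± 0.10 and 0.70 ± 0.02. At rps2/rps20/rpt3/rpl15 (III, 2095740-2100814) it was 2.10 ± 0.03 and 0.97 ± 0.07, and at the silencing gene clr2 (I, 4962498-4966844) 2.03 ± 0.08 and 0.91 ± 0.05. The remaining named regions were gmh6/SPBC1289.14 (2.38 ± 0.07), which overlapped an annotated LTR, ppa2/rip1 (2.30 ± 0.04), cwf10 (2.20 ± 0.07), SPCC18.17C/fum1/rpc34 (2.22 ± 0.08), met14/mug162/sst6 (2.20 ± 0.07) and nab3/spo20 (2.13 ± 0.03). The highest single Cbh1 probe of the array classes lay between the divergent genes fum1 and rpc34 (III, 1991174-1991233), at 4.18.

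Probes at tRNA genes lay above the array median, at 0.50 ± 0.15 for Abp1 and 0.25 ± 0.05 for Cbh1 (SD, n = 2 arrays each), with 31 of 287 and 23 of 292 probes enriched. Probes at 5S rRNA genes had 0.53 ± 0.40 and 0.29 ± 0.10, with 15 and 7 of 80 probes enriched. In the terminal 50 kb of chromosomes I and II, the mean was 0.48 ± 0.22 for Abp1, with 74 of 484 probes enriched, and 0.09 ± 0.01 for Cbh1, with 45 of 508. Mating-type probes had 0.44 ± 0.12 for Abp1 (17 of 104 enriched) and 0.29 ± 0.04 for Cbh1 (11 of 110), and all 11 of the latter were among the 36 mating-type probes without a match in ASM294v3. Sequence between divergent genes, which holds promoters on both sides, had 576 of 3636 probes enriched for Abp1 and 361 of 3784 for Cbh1. Sequence between tandem genes had 361 of 3609 and 258 of 3744, and between convergent genes 40 of 511 and 28 of 531. The mean log2 ratios of these classes were 0.35, 0.25 and 0.29 for Abp1 and 0.21, 0.14 and 0.14 for Cbh1. Gene bodies had 1013 of 30469 and 1154 of 31754 probes enriched, with mean log2 ratios of 0.06 and 0.08, medians of -0.03 and 0.00, and a camera (limma) test that pointed down for Abp1 (adjusted p = 7.50e-05). The gene body call was lost with an estimated correlation (adjusted p = 0.0742), although it passed there with the GC trend removed (adjusted p = 0.024 with an estimated correlation). For Cbh1, divergent and tandem sequence had means above 0 beside medians of -0.02 and -0.02 and a camera test that pointed down without passing.

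Centromere probes were not enriched as a class for either protein, at -0.08 ± 0.06 for Abp1 and -0.44 ± 0.16 for Cbh1 (SD, n = 2 arrays each). In limma, 4 of 273 probes were enriched for Abp1 and 14 of 281 were depleted for Cbh1, at a log2 ratio of -1 or lower. The Abp1 mean turned to 0.09 in the value table and to 0.03 over probes with 1 match (mean of the array means), where the Cbh1 mean was -0.15 and -0.21. Leaving out Abp1 replicate 1 gave an Abp1 mean of -0.12, and leaving out replicate 2 gave -0.04. The terminal 20 kb of chromosome III had -0.69 ± 0.05 and -0.98 ± 0.14. Only 7 of its 88 probes had 1 match, so these means come mostly from repeated sequence. Mitochondrial DNA was depleted at all 61 probes, at -3.60 ± 0.30 and -3.16 ± 0.24. In camera (limma) it passed with the preset correlation (adjusted p = 6.46e-78 for Abp1 and 1.81e-78 for Cbh1) and not with an estimated one (adjusted p = 0.202 and 0.297 with an estimated correlation).

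In camera (limma) with a preset correlation, the adjusted p for Abp1 was 5.85e-23 for tRNA genes, 1.02e-09 for 5S rRNA genes, 6.57e-18 for subtelomeres, 3.12e-08 for mating-type probes and 3.31e-05 for convergent sequence. It was 0.00357 for divergent and 0.00672 for tandem sequence, 0.00363 for centromeres (downwards) and 6.57e-18 for the ends of chromosome III (downwards). For Cbh1 it was 0.000494 for tRNA genes, 0.00488 for 5S rRNA genes, 0.00542 for mating-type probes, 2.32e-24 for centromeres and 2.22e-34 for the ends of chromosome III (both downwards), and above 0.05 for subtelomeres (0.854), divergent (0.894), tandem (0.894) and convergent sequence (0.854). The Cbh1 subtelomere mean of 0.09 was 0.35 in the value table and 0.33 over probes with 1 match, and it passed in both with the preset correlation, but not with an estimated correlation (adjusted p = 0.821 and 0.934). With an estimated correlation, every one of these calls was lost: the adjusted p for Abp1 was 0.278 with an estimated correlation for tRNA genes, 0.472 for 5S rRNA genes, 0.287 for subtelomeres, 0.202 for mating-type probes, 0.482 for divergent and tandem sequence, 0.472 for convergent sequence, 0.628 for centromeres, 0.202 for the ends of chromosome III and 0.0742 for gene bodies. For Cbh1 it was 0.793 with an estimated correlation for tRNA genes, 0.880 for 5S rRNA genes, 0.456 for mating-type probes and centromeres, and 0.193 for the ends of chromosome III. With 4 arrays, this form of camera has little power and was not passed even by mitochondrial DNA, depleted at all 61 probes. A loss there therefore leaves a class undecided. In circular shifts of the labels, tRNA and 5S rRNA genes reached the smallest possible p for Abp1 (0.000275 after adjustment). Divergent, tandem and convergent sequence did so too, as did gene bodies (downwards). The adjusted p was 0.00269 for subtelomeres, 0.00638 for the ends of chromosome III (downwards) and 0.0548 for centromeres, which did not pass. For Cbh1 it was 0.0283 for tRNA genes, 0.0508 for 5S rRNA genes, 0.000440 for divergent, 0.0454 for tandem and 0.443 for convergent sequence. Cbh1 subtelomeres had 0.905, and downwards, centromeres and gene bodies had 0.000440 and the ends of chromosome III 0.0165. Without Cbh1 replicate 1, the Cbh1 calls were lost for tRNA genes (0.21), 5S rRNA genes (0.22) and mating-type probes (0.27). Without Abp1 replicate 1, the Abp1 mean was 0.25 for 5S rRNA genes, 0.33 for subtelomeres, 0.21 for divergent and 0.18 for convergent sequence.

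By gene, the 500 bp upstream of 484 of 4970 measured genes had a log2 ratio of at least 1 at an adjusted p under 0.05 for Abp1, and 337 of 5066 did for Cbh1. The Abp1 count was 299 without Abp1 replicate 1. At an adjusted p under 0.05 alone, the rule used for the lists, 1103 of 4970 genes were higher than the median for Abp1 and 786 of 5066 for Cbh1. The list counts below are to be read against these shares of all genes, and a count near them does not set a list apart. Among 17 silencing genes, 6 rose above the median for Abp1 over all genes and 8 adjusted over the list alone, and 4 rose for Cbh1 (5 adjusted over the list alone). Upstream of ago1, which encodes Argonaute, the Abp1 ratio was 2.18 ± 0.14 (SE), measured on replicate 2 only. Upstream of rik1, of the histone H3 lysine methyltransferase complex, it was 1.45 ± 0.14 for Abp1, on replicate 1 only, and 1.70 ± 0.10 for Cbh1. Upstream of clr2 it was 2.12 ± 0.15 and 3.30 ± 0.15, on 1 array each and so with a spread from the limma prior alone, and upstream of the telomere gene taz1 1.1 ± 0.13 for Cbh1. Upstream of set1 the Cbh1 ratio was lower than the median, at -0.71 ± 0.17, a call that was lost at -0.46 without Cbh1 replicate 2. Of the ribosomal protein genes, 26 of 129 rose for Abp1 over all genes (24 adjusted over the list alone) and 32 of 130 for Cbh1 (33 adjusted over the list alone). This share was under that of all genes for Abp1 and above it for Cbh1. Genes that rose included rpl35A02 (2.84 ± 0.15 for Abp1 and 2.19 ± 0.15 for Cbh1), rps1101 (2.17 ± 0.10 for Abp1), rpl15 (3.16 ± 0.13 for Cbh1) and rpl6 (3.14 ± 0.12 for Cbh1). Also among them was rps801 (1.91 ± 0.14 for Abp1, 1 array), in a window that reaches an annotated LTR. The list as a whole passed camera in limma for Cbh1 (adjusted p = 0.000393), a call that was lost with an estimated correlation (adjusted p = 0.933 with an estimated correlation) and without Abp1 replicate 1 (adjusted p = 0.127), and did not pass for Abp1 (adjusted p = 0.181). No other list passed camera for either protein.

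Of 19 nitrogen and nutrient transport genes, 6 rose for Abp1 and 4 for Cbh1, with isp4 lower for Cbh1 (-0.56 ± 0.12, or -0.34 and not called without Cbh1 replicate 2), and the counts were the same adjusted over the list alone. The ammonium transporter gene amt3 had 2.46 ± 0.11 for Abp1 and 2.31 ± 0.11 for Cbh1 (SE), in a window that reaches Tf2-3. The proline permease gene put4 had 0.63 ± 0.10 and 1.35 ± 0.10, and the malate transporter gene mae1 had 0.80 ± 0.14 for Abp1, or 0.46 without Abp1 replicate 1. Among 20 mating and meiosis genes, 2 rose and 1 fell below the median for Abp1, the same adjusted over the list alone, and 5 rose and 1 fell for Cbh1 (5 and 3 adjusted over the list alone). The pheromone gene map2 had 0.99 ± 0.10 and 1.40 ± 0.10, the mating-type regulator gene map1 had 1.03 ± 0.15 for Abp1 on 1 array, and ste4 had 0.78 ± 0.10 for Cbh1. The Cbh1 call of mam2 (0.52 ± 0.10) was lost at 0.45 without Cbh1 replicate 2. Of 16 core stress genes, 3 rose for Abp1 and 4 for Cbh1 over all genes and adjusted over the list alone, with the catalase gene ctt1 highest for Cbh1 (1.28 ± 0.10, adjusted p = 2.07e-06 in limma) and hsp104, a disaggregase gene, highest for Abp1 (0.83 ± 0.10). Of 11 chaperone genes, 2 rose for Abp1 (hsp104 and hsp10, 0.46 ± 0.10) and 1 for Cbh1 (hsp10, 0.85 ± 0.10), the same adjusted over the list alone. The window of hsp10 reaches annotated LTRs, which lay in no enriched region of either protein.

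Of 13 glycolysis and fermentation genes, 2 rose and 2 fell for Abp1 (3 and 2 adjusted over the list alone), and 1 rose and 3 fell for Cbh1 (4 and 3 adjusted over the list alone). The phosphoglycerate mutase gene gpm1 had 1.45 ± 0.10 (SE) for Cbh1 and 0.40 ± 0.10 for Abp1, the latter call being lost at 0.30 without Abp1 replicate 1. Of 9 histone genes, limma called 0 for Abp1 over all genes and adjusted over the list alone, with 7 at an unadjusted p under 0.05, and 2 for Cbh1 over all genes and adjusted over the list alone (hht1, 0.78 ± 0.11, and hhf1, 0.63 ± 0.10, or 0.54 and not called without Cbh1 replicate 2). Of 13 iron and copper genes, 1 rose for each protein, the same adjusted over the list alone, with the iron-responsive repressor gene fep1 at 0.58 ± 0.10 for Abp1 and str2 at 0.61 ± 0.11 for Cbh1, or 0.48 and not called without Cbh1 replicate 2. Of 4 phosphate genes, 1 rose for Abp1 (2 adjusted over the list alone) and 1 for Cbh1 (1 adjusted over the list alone), the acid phosphatase gene pho4, at 0.96 ± 0.12 and 0.84 ± 0.12. Of the G1-S genes, 2 of 6 rose for Abp1 and 1 of 7 for Cbh1, the same adjusted over the list alone. The replication licensing gene cdc18 had 1.08 ± 0.11 for Abp1 and 0.63 ± 0.11 for Cbh1, the latter call being lost at 0.57 without Cbh1 replicate 2, and cdc22 had 0.38 ± 0.10 for Abp1, lost at 0.32 without Abp1 replicate 2. For Abp1, the mean of the glycolysis, iron and mating lists was above 0 while camera pointed down. For Cbh1, camera pointed down for iron with a mean of 0.01, and the core stress list had a median of -0.01 beside a mean of 0.20.

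The CENP-B family genes themselves carried signal. Upstream of cbh1 (SPAC9E9.10C; I, 4458920-4460878), the ratio was 0.95 ± 0.15 (SE) for Abp1, on replicate 2 only, and 0.90 ± 0.11 for Cbh1 (adjusted p = 0.000172 in limma). Upstream of cbh2 (SPBC14F5.12C; II, 4180737-4182438), it was 0.48 ± 0.11 for Abp1 and 0.55 ± 0.11 for Cbh1, the latter call being lost at 0.38 without Cbh1 replicate 1. Upstream of cbp1 (SPBC1105.04C; II, 3510427-3512370), which encodes Abp1, it was 0.55 ± 0.13 for Abp1, a call lost at 0.32 without Abp1 replicate 2, and 0.01 ± 0.13 for Cbh1. In all, 3 of the 3 genes were called above the median for Abp1 and 2 of 3 for Cbh1, over all genes and adjusted over the list alone. For either protein, 0 of the 3 reached a log2 ratio of 1.

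The second comparison asked where the proteins differed. Of 39875 probes, 5404 differed between Abp1 and Cbh1 in limma at an adjusted p under 0.05, with 3320 higher for Abp1 and 2084 higher for Cbh1. Without Abp1 replicate 1 these counts were 1671 and 1486, and those with a difference of at least 1 on the log2 scale went from 956 and 542 to 401 and 501. Tf2 elements were higher for Cbh1, with a mean Abp1 minus Cbh1 difference of -0.43 and 51 of 91 probes lower for Abp1, but the difference turned to 0.05 over the Tf2 probes with 1 match, 7 of 9 of which lie within 400 bp of an element end. LTRs outside Tf2 were higher for Abp1, by 0.46, with 46 of 115 probes higher, but by 0.10 without Abp1 replicate 1. Over Tf2 probes, both Cbh1 arrays lay above both Abp1 arrays, and along the element the difference went from 0.28 within 400 bp of an end to -0.72 in the middle. Abp1 was also higher at subtelomeres (0.42), centromeres (0.36), the ends of chromosome III (0.31), 5S rRNA genes (0.29), tRNA genes (0.27), convergent (0.16), divergent (0.15) and tandem sequence (0.12) and mating-type probes (0.15, or 0.055 and not called in the value table), and lower at mitochondrial probes (-0.45). In gene bodies the mean difference was -0.02, but it turned to 0.005 when arrays were centred on gene bodies, and more gene body probes were higher for Abp1 (1775) than for Cbh1 (1610). Of the centromere probes, 61 were higher for Abp1, as were 168 subtelomere probes.

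In camera (limma), the preset correlation gave adjusted p = 3.48e-17 for Tf2, 1.06e-06 for LTRs, 1.06e-18 for subtelomeres, 9.40e-18 for centromeres, 2.22e-07 for the ends of chromosome III, 2.81e-12 for tRNA genes, 0.000611 for 5S rRNA genes, 0.00621 for mating-type probes, 0.000918 for divergent, 0.00351 for tandem and 0.000153 for convergent sequence, 2.81e-12 for mitochondrial probes and 1.10e-06 for gene bodies. Circular shifts of the labels gave a permutation p after adjustment of 0.0011 for Tf2, 0.00122 for subtelomeres, 0.00616 for centromeres and 0.000943 for 5S rRNA genes. For LTRs, tRNA genes, gene bodies and divergent, tandem and convergent sequence it was 0.000367, the smallest possible here, and the ends of chromosome III (0.23) did not pass. Mating-type and mitochondrial probes had no shift test. With an estimated correlation each of these camera calls was lost: the adjusted p was 0.0526 with an estimated correlation for Tf2 and gene bodies (0.0338 for gene bodies with the GC trend removed), 0.557 for 5S rRNA genes and 0.439 for LTRs, subtelomeres, centromeres, the ends of chromosome III, tRNA genes, mating-type probes, mitochondrial probes and divergent, tandem and convergent sequence. Without Abp1 replicate 1, the difference was 0.23 at subtelomeres, 0.17 at tRNA genes, 0.06 at divergent and 0.08 at convergent sequence and -0.23 at mitochondrial probes, changed sign at 5S rRNA genes (-0.03), and was lost at tandem sequence (0.05) and mating-type probes (0.10). Without Abp1 replicate 2 it was 0.51 at 5S rRNA genes. Without Cbh1 replicate 1 it was -0.28 at mitochondrial probes. Without Cbh1 replicate 2, tandem sequence (0.08) was lost, convergent sequence had 0.10 and the count of differing probes was 2201, against 3157 without Abp1 replicate 1 and 3395 without Cbh1 replicate 1.

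Runs of differing probes formed 555 regions higher for Abp1 and 266 higher for Cbh1. Annotated LTRs were overlapped by 54 of the former and 6 of the latter, while 11 of the latter touched 8 Tf2 elements. The largest differences in favour of Abp1 lay at dlp1 and the telomere complex gene poz1 (I, 4069656-4071535), with 1.63 ± 0.13 for Abp1 and -0.04 ± 0.07 for Cbh1 (SD, n = 2 arrays each), and at the nicotinamidase gene pnc1 and csr103 (II, 2496826-2501183), with 1.44 ± 0.17 and -0.15 ± 0.12. At crr1/inp2 (II, 1657985-1660596) the ratios were 1.41 ± 0.24 and -0.06 ± 0.09, at spo14/mcs2 (II, 1891551-1893362) 1.57 ± 0.06 and 0.22 ± 0.03, and at cdc22/hsp3105 (I, 4228840-4232757) 1.40 ± 0.07 and 0.04 ± 0.05. At pld1/mrf1 (I, 569328-570469) the difference of 1.59 was 0.87 without Abp1 replicate 1. The largest differences in favour of Cbh1 lay at prp28/pup3/SPCC63.13/eis1 (III, 857266-863185), with 0.12 ± 0.00 for Abp1 and 1.72 ± 0.02 for Cbh1, and at pof9/SPBC3H7.04/kgd1 (II, 1872177-1879704), with 0.21 ± 0.03 and 1.71 ± 0.01. At fzo1, a mitochondrial fusion gene, and rpl803 (II, 596907-601260) the ratios were 0.26 ± 0.04 and 1.66 ± 0.00, at smc5/dad3/mek1 (I, 5227275-5233410) 0.06 ± 0.02 and 1.27 ± 0.16, and at the glycerol-3-phosphate dehydrogenase gene gut2 (III, 1840248-1847228) 0.81 ± 0.01 and 1.97 ± 0.01.

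**Figure D4:**
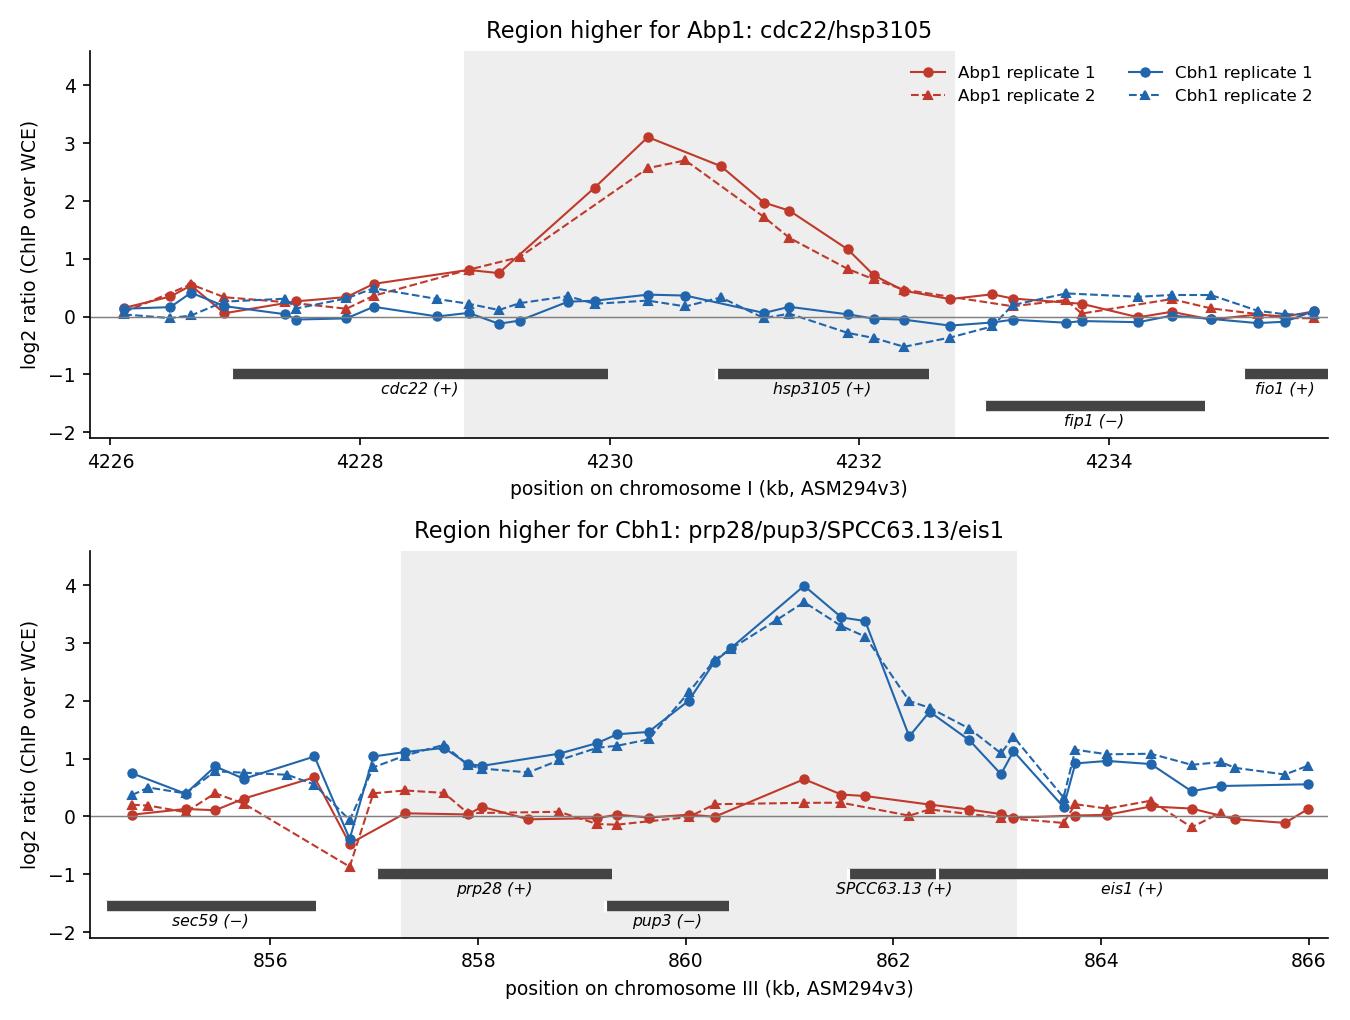
Log2 ratio of each array over whole cell extract (WCE) along a locus higher for Abp1 (top) and 1 higher for Cbh1 (bottom), with points for probes, lines that pass across missing spots, bars for genes with their strand, and the region of differing probes shaded. Over the shaded parts, the means were 1.40 for Abp1 and 0.04 for Cbh1 at cdc22/hsp3105, and 0.12 and 1.72 at prp28/pup3/SPCC63.13/eis1.

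Upstream of genes, 456 of 4970 were higher for Abp1 and 190 higher for Cbh1 at an adjusted p under 0.05. Of the ribosomal protein genes, 8 of 129 were higher for Abp1 and 9 higher for Cbh1 over all genes and adjusted over the list alone, with differences of 1.22 at rps1101, -1.34 at rpl15 and -1.64 at rpl6. Of the 17 silencing genes, 2 were higher for Abp1, ago1 (1.88) and clr3 (0.75), and 1 higher for Cbh1, clr2 (-1.18), the same adjusted over the list alone. The clr2 value was measured on 1 array of each protein, so its spread came from the limma prior alone and the call was lost with a trended and robust prior (adjusted p = 0.111 in limma). The clr3 call was lost without Cbh1 replicate 2 (0.48). The difference was 0.84 at fep1 and -0.64 at str2 (iron and copper, 1 each way, the same adjusted over the list alone), and 0.81 at mae1 and -0.73 at put4 (nitrogen and nutrient transport, 2 and 1, the same adjusted over the list alone). It was 0.95 at map1, -0.78 at ste4 and -0.76 at mam2 (mating, 1 and 2, or 2 and 2 adjusted over the list alone). It was 0.57 at hsp104, the 1 chaperone gene called, also adjusted over the list alone, and -1.12 at ctt1 (core stress, 1 each way, the same adjusted over the list alone). The 1 glycolysis gene called was gpm1 (-1.05) and the 1 histone gene was hht1 (-0.54), each also adjusted over the list alone. In limma, 0 of the 6 G1-S genes differed over all genes (2 at an unadjusted p under 0.05, 1 adjusted over the list alone), 0 of the 3 CENP-B family genes (1 at an unadjusted p under 0.05, 1 adjusted over the list alone), and 0 of the 4 phosphate genes (0 at an unadjusted p under 0.05 and 0 adjusted over the list alone). Of the 17 named genes with a called difference, 6 kept the call with each array left out, 9 lost it with at least 1 array left out, and ago1 and clr2 had no value once an array that alone carried them was left out. For hsp104 and hht1 this held without Abp1 replicate 1 (0.47 at hsp104) and without either Cbh1 replicate (0.66 and 0.49 at hsp104, -0.63 and -0.44 at hht1). The mae1 difference was 0.46 and not called without Abp1 replicate 1, and was also not called without either Cbh1 replicate (0.78 and 0.83), and put4 was lost without either Cbh1 replicate (-0.70 and -0.75). Single losses were ste4 (-0.72) without Cbh1 replicate 1, and str2 (-0.50), map1 (0.85) and mam2 (-0.69) without Cbh1 replicate 2, while map1 had no value without Abp1 replicate 1. Other alternatives ended calls too. That of hht1 was kept in 9 of 16, being lost also with centring on gene bodies (-0.51), with a trended and robust prior and with windows of 250 bp (-0.54) and 1000 bp (-0.28). Over gene bodies in place of upstream windows, gpm1 (-0.30), fep1 (0.15), map1 (0.15), mae1 (0.22) and hsp104 (0.005) were not called, and with 250 bp upstream mae1 (0.95) and clr3 (0.80) were not called and ago1 and clr2 had no value. No list passed camera for the difference. Mean, median and test differed in sign for the core stress, glycolysis, histone, iron, nitrogen and phosphate lists.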

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

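Of the tests below, 2 of the 3 on the width of Cbh1 regions were written down before their values had been seen, those on pressed-down peak tops and on peak height. The test on fragment length, the tests on centromeres and the tests on Tf2 and LTRs were chosen after the results had been seen. The class, region and gene values listed first stand out because Abp1 and Cbh1 differed in a test of the difference itself, with 2 arrays per protein. The width of Cbh1 regions and the centromeres were taken up without such a test.

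In limma, 5404 probes differed between Abp1 and Cbh1 at an adjusted p under 0.05. By class, the mean Abp1 minus Cbh1 difference passed camera with a preset correlation at Tf2 elements (-0.427), LTRs (0.464), centromeres (0.362), mating-type probes (0.147, or 0.055 and not called in the value table), subtelomeres (0.421), tRNA genes (0.268), 5S rRNA genes (0.293), gene bodies (-0.024, or 0.005 with centring on gene bodies), divergent (0.153), tandem (0.121) and convergent sequence (0.160) and mitochondrial probes (-0.451). None of these 12 passed with an estimated correlation, where the lowest adjusted p was 0.0526, although gene bodies did with the GC trend removed (adjusted p = 0.0338 with an estimated correlation). Without Abp1 replicate 1, mating-type probes (0.103) and tandem sequence (0.052) no longer passed, the 5S rRNA genes changed sign (-0.025), and the difference was 0.10 at LTRs, 0.233 at subtelomeres, 0.169 at tRNA genes, 0.064 at divergent sequence, 0.081 at convergent sequence and -0.229 at mitochondrial probes. The count of differing probes was then 3157, with 1671 higher for Abp1 and 1486 higher for Cbh1.

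Regions of differing probes with the highest difference in favour of Abp1 were dlp1/poz1 (1.681), pnc1/SPBC557.05/csr103 (1.626), pld1/mrf1 (1.588, or 0.866 without Abp1 replicate 1), crr1/inp2 (1.582), csc1/rav2/trm141 (1.487), pkl1/pfd6/rpt5 (1.464), spo14/mcs2 (1.417), pvg1 (1.414), SPCC18B5.05C/dom34/nup61 (1.401) and cdc22/hsp3105 (1.399). Those with the highest difference in favour of Cbh1 were prp28/pup3/SPCC63.13/eis1 (-1.573), pof9/SPBC3H7.05C/SPBC3H7.04/kgd1 (-1.481), fzo1/aly1/dcn1/rpl803 (-1.388), SPCC1235.01/bio2 (-1.279), the stretch on chromosome I without a protein-coding gene (-1.250), mfc1/SPAPB1A11.02 (-1.249), smc5/dad3/mek1 (-1.241), nit1/gyp10 (-1.231), gut2/set11/spc19 (-1.228) and bpb1/SPCC1672.01 (-1.194).

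Upstream of genes, limma called a difference in favour of Abp1 at hsp104 (0.574), fep1 (0.843), map1 (0.947), mae1 (0.806), rps1101 (1.218), ago1 (1.880) and clr3 (0.745). It called a difference in favour of Cbh1 at ctt1 (-1.120), gpm1 (-1.045), hht1 (-0.538), str2 (-0.638), ste4 (-0.783), mam2 (-0.764), put4 (-0.725), rpl15 (-1.344), rpl6 (-1.638) and clr2 (-1.179). The values at ago1 and map1 rest on 1 Abp1 array and that at clr2 on 1 array of each protein, so the clr2 call took its spread from the prior alone, and leaving out an array that alone carried a value left ago1, map1 or clr2 without one. Calls were lost with at least 1 array left out at hsp104 (0.472 without Abp1 replicate 1), hht1 (-0.443 without Cbh1 replicate 2), mae1 (0.462 without Abp1 replicate 1), clr3 (0.482 without Cbh1 replicate 2), str2 (-0.504 without Cbh1 replicate 2), map1 (0.848 without Cbh1 replicate 2), mam2 (-0.687 without Cbh1 replicate 2), put4 (-0.701 without Cbh1 replicate 1) and ste4 (-0.723 without Cbh1 replicate 1).

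Cbh1 regions without an LTR or Tf2 element were wider than those at LTRs, with medians of 1825 and 1304 bp. By the median, this held only for the 98 that overlapped an Abp1 region (2722 bp). The 37 that overlapped none were narrower (583 bp). The share of signal left in the flanks differed by 0.088 ± 0.01 between the kinds (SD over the 2 Cbh1 arrays), which restates the widths. At Cbh1 regions with an LTR it was 0.037 higher on the Cbh1 than on the Abp1 arrays. At Abp1 regions with an LTR, however, it was 0.076 and 0.147 on the Cbh1 arrays and 0.086 and 0.09 on the Abp1 arrays. Longer DNA fragments in the Cbh1 samples therefore stay open. Peak tops pressed down by LOWESS do not account for the difference in flank share between the kinds. It was 0.094 without saturated spots or in the value table, whichever was smaller, and 0.106 in the other. Both used the regions of the main setting. Saturation stays open, since leaving out saturated spots removes pressed-down tops and does not restore them. Within 6 strata of similar peak height over 226 regions, the median width still differed by 264 bp, without passing (permutation p = 0.147). A test that does not pass cannot show that height removes the difference, so taller peaks stay open as an account of the width. A different mode of Cbh1 binding stays open as well and was not tested.

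Centromere probes were not enriched for either protein, at -0.08 for Abp1 and -0.44 for Cbh1. LOWESS normalization of bright repeat probes does not account for the lack of enrichment, since the value table, which has no LOWESS, gave 0.085 for Abp1 and -0.145 for Cbh1, far under the log2 ratio of 1, although these values lie closer to or above 0. The 42 centromere probes with 1 exact match had 0.029 and -0.21. Only exact matches were counted, so near copies of these sequences could still mix in their signal. Mixing of bound and unbound copies therefore stays open, above all for the probes with several matches, which include all 4 enriched Abp1 probes. Mean ratios at centromeres thus lay under the threshold on every array, and low occupancy may be the reason. Loss of centromeric DNA during crosslinking or amplification was not tested, and no untagged control was used here.

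Tf2 elements had higher ratios for Cbh1 and LTRs outside Tf2 higher ratios for Abp1. LOWESS does not account for the opposite signs, since the value table gave -0.697 at Tf2 and 0.335 at LTRs, and neither do spots marked as outliers, since keeping them gave -0.448 and 0.412. The difference fell with distance from the element end over 91 Tf2 probes (Spearman's rho = -0.654, permutation p = 1e-05, the smallest that 100000 permutations can give), with rho of -0.879 for Abp1 and -0.73 for Cbh1, but 85 of the 94 Tf2 probes share sequence between elements and are not independent, so this p overstates the evidence. It may be that Abp1 sits mainly at the LTRs that flank each element and Cbh1 reaches further inside, a hypothesis found and tested on the same data. The LTR part rests largely on Abp1 replicate 1, without which the LTR difference was 0.10 and that of Tf2 stayed in favour of Cbh1, while the 9 Tf2 probes with 1 match, 7 of them within 400 bp of an end, gave 0.053.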

How the results depend on the processing

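Keeping spots marked as outliers was the 1 alternative chosen after seeing the data. Over all alternatives, 1146 values of results that answer a comparison kept their direction and their side of the threshold, as did 80 values with outlier spots kept. Of the other values of these results, 21 were counts that moved, 6 changed sign, 15 lost a call and 6 gained one. Values of single genes and regions kept theirs in 2131 and 161 cases, lost a call in 54 and 2, and gained one in 78 and 1. A further 9 changed sign. Where a call or sign changed below, the cause was not tested, except that a lower or higher threshold changes counts by construction. Slide was not run as a block because each array had its own.

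With normexp background correction, 4031 probes were enriched for Abp1 and 3435 for Cbh1, and the Cbh1 means of tRNA genes (0.319) and 5S rRNA genes (0.393) no longer passed. The lower threshold gave 4463 and 3731 probes and 382 Cbh1 regions, and the higher threshold of 1.5 gave 1051 and 1214 probes, 260 Abp1 regions and an overlap of 131. A log2 ratio of 1 on both arrays without a test gave 879 Abp1 and 1612 Cbh1 probes, 231 Abp1 and 222 Cbh1 regions and an overlap of 115, so Abp1 then had fewer probes than Cbh1. It needs a value on both arrays, which 10911 Abp1 probes lack. With only probes with 1 match, the Tf2 difference was 0.053 and the Abp1 centromere mean over fitted probe values 0.021 (0.029 as the mean of the array means), both of the opposite sign, the Cbh1 mating-type mean (0.070) no longer passed, and the Cbh1 subtelomere mean (0.333) did, though not with an estimated correlation (adjusted p = 0.934).

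With the value table, the Abp1 centromere mean was 0.085 and eno101 had 0.045 for Cbh1, both of the opposite sign. The mating-type difference (0.055), the Cbh1 means of tRNA genes (0.222) and 5S rRNA genes (0.298) and the Abp1 means of divergent (0.341) and tandem sequence (0.239) no longer passed, and the Cbh1 subtelomere mean (0.352) did, though not with an estimated correlation (adjusted p = 0.821). The median in place of the mean gave -0.025 for Abp1 in gene bodies, and centring on gene bodies gave 0.005 for the gene body difference.

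With gene bodies in place of upstream windows, 168 genes were enriched for Abp1 and 213 for Cbh1, and the glycolysis list for Cbh1 (0.277) and the ribosomal protein list for Abp1 (0.294) passed with the preset correlation and not with an estimated correlation (adjusted p = 0.747 and 0.676). Values of the opposite sign were then found at cta3 (-0.074), pfk1 (0.167), hht3 (0.235), fep1 (-0.006), mfm3 (-0.213) and rps802 (0.462) for Abp1 and at eno101 (0.070) and htb1 (0.234) for Cbh1. With 250 bp upstream, 321 genes were enriched for Abp1, and the ribosomal protein list for Abp1 (0.297) and the mating difference (-0.112) passed with the preset correlation and not with an estimated correlation (adjusted p = 0.654 and 0.951).

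Leaving out 1 array at a time gave 1210 to 2357 enriched Abp1 probes, 289 to 495 Abp1 regions, 2201 to 6444 differing probes and 299 to 524 genes enriched for Abp1. The Cbh1 means ranged from 0.266 to 0.320 at mating-type probes, 0.211 to 0.288 at tRNA genes, 0.222 to 0.358 at 5S rRNA genes and 0.276 to 0.289 over ribosomal protein genes. The differences ranged from 0.103 to 0.218 at mating-type probes, from -0.025 to 0.510 at 5S rRNA genes and from 0.052 to 0.167 in tandem sequence. The remaining array of a group was assumed to vary like the other group.

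Across 28363 probes, the replicate 1 minus replicate 2 differences of Abp1 and of Cbh1 had a correlation of 0.165. The sources do not say whether the numbers pair the samples, and 2 pairs cannot settle it. With the replicate number as a block, 6223 probes differed (3776 higher for Abp1 and 2447 for Cbh1), or 5409 with the GC trend removed too, and no class or list call changed. Signal over background of 4.30 to 5.83 leaves weak ratios open to background.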

Other observations

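The tests on LTR length and on the distance of tRNA genes from LTRs, and the subsets of probes below, were chosen after the results had been seen. Probes at the 36 mating-type sequences without a match in ASM294v3 had 0.69 ± 0.00 for Cbh1 and 0.48 ± 0.18 for Abp1 (SD, n = 2 arrays each), with 11 and 7 enriched. The 74 with a match had 0.09 ± 0.06 and 0.41 ± 0.09, and 18 of them were higher for Abp1 by limma. A set of 129 probes whose names begin with pNSU had -0.64 ± 0.08 for Cbh1 and -0.04 ± 0.07 for Abp1, with 84 higher for Abp1. Over the 25 probes at tRNA genes inside centromeres, Abp1 had 0.33 ± 0.11 and Cbh1 -0.03 ± 0.15.

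Ratios over the bodies of the CENP-B family genes differed by gene and protein. Over the 7 probes of cbh1, the ratio was 0.82 ± 0.07 for Abp1 and 0.57 ± 0.05 for Cbh1, with 1 probe enriched for each. Over the 7 probes of cbp1 it was 0.50 ± 0.17 for Abp1, with 1 enriched, and 0.03 ± 0.02 for Cbh1, with 0 enriched. Over the 5 probes of cbh2 it was 0.16 ± 0.13 and 0.41 ± 0.09, with 0 enriched for either. Intergenic binding was seen away from annotated LTRs too, although ratios around LTRs stayed raised past the 1 kb limit used here. Over 1 kb from any LTR, 412 of 3342 probes between divergent genes (12.3%) were enriched for Abp1 and 225 of 3465 (6.49%) for Cbh1, against 781 of 29828 (2.62%) and 911 of 31068 (2.93%) in gene bodies.

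Longer annotated LTRs were more often in an enriched region, and 1 hypothesis is that the length of the LTR sets the ratio. Across LTRs outside Tf2 with a measured probe, which are not independent replicates, Spearman's rho of length and ratio was 0.189 for Abp1 (108 LTRs, permutation p = 0.0497) and 0.284 for Cbh1 (121 LTRs, permutation p = 0.00167). The Abp1 p lies at the threshold within resampling error, and 2 relations were computed. The test leaves the hypothesis undecided, and short LTRs also hold fewer probes.

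Probes at tRNA genes lay above the median for Abp1. The 278 tRNA probes over 1 kb from any LTR kept a mean of 0.475 ± 0.142. Around LTRs at least 5 kb from a Tf2 element, however, the Abp1 mean was 0.514 at -1500 bp and 0.496 at 1500 bp. It was 0.382 at -2000 bp and 0.417 at 2000 bp. A limit of 1 kb therefore cannot exclude spread from annotated LTRs, which stays open, and other causes were not tested.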
